A study of Mus musculus with 12 samples.

How the data were processed

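The samples are cancer cells from lung tumours of mice on a mixed BL6/129 background. KT is the background shared by all groups, and the KT group is the reference. The alternative sample names in the labels name lentiviral Cre for KT replicates 2 to 4 but not for replicate 1, so whether all KT tumours were started in the same way is open. Lkb1, encoded by Stk11, is a kinase that activates a family of related kinases, among them the salt-inducible kinases Sik1, Sik2 and Sik3. SIKs phosphorylate CRTC coactivators and class IIa histone deacetylases, so their loss frees CRTCs to activate CREB targets. KT;Lkb1f/f tumours carry floxed Stk11 alleles, and the H11LSL-Cas9 tumours carry a Cre-dependent Cas9 allele with guide RNAs against Sik genes.

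Per the labels, tumours were digested with collagenase IV, dispase and trypsin at 37C for 30 min, and cells positive for CD45, CD31, F4/80 or Ter119 were excluded by flow cytometry. RNA from the sorted cells was amplified to cDNA with the Ovation kit, made into TruSeq DNA libraries and sequenced as read pairs of 100 bases on a HiSeq instrument. Amplification from small numbers of cells adds spread between libraries, and the counts carry no molecule tags that would separate copies from molecules. Per the submitters' processing notes, reads were handled with STAR 2.4.2a, HTSeq (no version stated) and the mm10 genome. The annotation and the strand setting are not given in the sources used here. The deposited values are counts per gene symbol, as made by the authors, in 1 table of 30743 genes or transcripts and 12 libraries, and every column was matched to a sample by its title. Values were whole numbers that summed to between 3847760 and 13955181 per library. No pair of libraries in a group was a duplicate: the lowest chi-square per degree of freedom between libraries of a group was 17.4.

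Symbols were matched to a RefSeq table of mm10 (GRCm38) for coordinates: 20855 matched directly, 2194 more by an older symbol, and 7694 had no match and were kept in the tests. Coordinates printed for Stk11, Sik1, Sik2 and Sik3 span the whole gene, exons, introns and untranslated regions together, and counts over exons do not show where a guide acts or which exons are floxed. Guide sequences and allele maps were not analysed here.

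Genes were tested with edgeR 4.0.16 in R 4.3.3: normalization by trimmed mean of M values (TMM), the filterByExpr filter by group, a robust quasi-likelihood fit and a 2-sided F test, with Benjamini-Hochberg adjustment over tested genes and a threshold of 0.05 without a minimum fold. The comparisons of Lkb1 deletion with KT, Sik targeting with KT and Lkb1 deletion with Sik targeting came from 1 fit of all 12 libraries in 3 genotype groups (13575 genes, common dispersion 0.262). The comparisons of sgSik1 and sgSik1-3 with KT and with each other came from a fit in 4 title groups (15303 genes, common dispersion 0.287). All groups in a fit share the estimate of the spread, because groups hold 2 to 5 libraries. The SE of a log2 change is its absolute value over the square root of F. CPM were computed on TMM effective library sizes.

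A count of 3 summed over a group was taken as the floor, which corresponds to 0.164 to 0.853 CPM in single libraries on TMM effective sizes. Where a group had 0 counts the fold is given as a bound from this floor, and where it had 1 to 3 counts as a ratio with its 95% binomial interval. These intervals and bounds cover counting error only.

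Genes were named by a rule set before their values were seen. It names the 4 targets, the 10 largest changes in each direction for the first 2 comparisons and the 5 largest for the others. Each of these had to pass the threshold, have a mean of at least 2 CPM over all libraries and show no overlap between the groups. The rule adds the 5 shared genes per direction with the largest smaller change, and up to 4 members of each list with the smallest p. Predicted genes, clones, Xist, Tsix and Y-linked, mitochondrial and antigen-receptor genes were counted but not named.

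A set of 34 gene lists (592 entries, 570 of them in the table) was fixed before the counts were seen: AT2 identity, AT1, club and ciliated markers, gastric and gut, squamous and basal, neuroendocrine, chromatin and embryonic progression, CREB and CRTC targets, LKB1 complex and substrate kinases, mesenchymal and EMT, epithelial, cell cycle, glycolysis and hypoxia, lipid and sterol synthesis, amino acid stress and serine synthesis, oxidative phosphorylation, chemokines and NF-kB response, interferon response, MHC class I, MHC class II, MAPK output, YAP and TEAD targets, TGF-beta and matrix proteases, dissociation response, and markers of leukocytes, macrophages, neutrophils, T and NK cells, B and plasma cells, endothelium, fibroblasts and pericytes, and erythroid cells. The list of mitochondrially encoded genes had 0 members in the table and gave no result. For each list, members past the threshold were counted over all genes and after adjustment over the list alone. Lists of at least 4 tested members were also compared with all other genes by camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists within a comparison, and again with the correlation between genes estimated from the data.

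The recovery of known changes was tested on simulated data, with counts drawn at the real depths and dispersions and 50 genes changed at each of 4 folds. Changes of 2-, 4-, 8- and 16-fold were called in 2, 30, 64 and 74% of genes for Lkb1 deletion against KT (5 of 90 calls were false), in 2, 40, 74 and 92% for Sik targeting against KT (4 of 108), and in 6, 40, 64 and 88% for Lkb1 deletion against Sik targeting (5 of 104). A change of 2-fold in a single gene was thus rarely detectable. With the cell cycle list shifted 2-fold, camera called it and 0 of the other 27 lists. That single draw made genes vary independently, so it cannot show how camera behaves when the genes of a list vary together.

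Genes changed both by Lkb1 deletion and by Sik targeting were counted per direction, beside the number expected for independent lists. Because both comparisons share the KT libraries, unchanged groups were also simulated 20 times. In these simulations the KT libraries were redrawn as well: new groups drawn around the mean of the real KT libraries would have cancelled the deviation that both comparisons share. The counts were also taken with the KT libraries split 2 and 2 between the comparisons, in 6 ways.

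Alternatives, tried 1 at a time, were median-ratio size factors, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (1 CPM in at least 4 libraries), a fit of only the groups compared, 4 title groups in place of 3 genotype groups, the replicate number as a block, and leaving out each library. For lists, the estimated correlation and the fry test were added. Chosen after seeing the data were the fits without KT replicates 2 and 3 and without the 4 most abundant transcripts (22 settings for genes besides the one reported). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.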

Results

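RNA was sequenced from cancer cells sorted out of mouse lung tumours of 4 kinds: KT tumours (4 libraries), KT tumours with Lkb1 (Stk11) deleted (3 libraries), and KT tumours with Cas9 and guides against Sik genes, titled sgSik1 (3 libraries) or sgSik1-3 (2 libraries). The genotype label pools the last 5 libraries, which are called Sik-targeted here. The titles and genotype labels do not say what the range in sgSik1-3 covers, nor whether libraries of a group come from separate animals. Alternative sample names in the labels name lentiviral Cre for KT replicates 2 to 4 but not for replicate 1. These names also include animal and tumour numbers, which may bear on whether animals were separate. For the samples titled sgSik1-3 they include the text Sik3x, which may bear on the range. Beyond the mention of Cre the names were not interpreted, so the range and the separation of animals stay open here. The p values therefore measure the spread between libraries, which may be technical. Total counts per library were 3847760, 8101304, 6675142 and 4146438 in KT replicates 1 to 4, and 9460177, 8753813 and 6427769 in Lkb1-deleted replicates 1 to 3. They were 8941240, 9219809 and 13955181 in sgSik1 replicates 1 to 3, and 5666378 and 7956660 in sgSik1-3 replicates 1 and 2. Adjusted p values of genes are edgeR quasi-likelihood p values after Benjamini-Hochberg adjustment over all tested genes, and a gene passed at 0.05. Changes are log2 fold changes with their standard error (SE), and levels are CPM (counts scaled to library size), mean and standard deviation (SD) over libraries.

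Stk11 (chromosome 10, 80115803 to 80130682, plus strand) stood at 44.7, 39.1, 40.9 and 31.0 CPM in KT replicates 1 to 4 and at 9.23, 16.6 and 9.92 in the Lkb1-deleted replicates. It stood at 137, 22.6 and 30.1 CPM in sgSik1 and at 32.6 and 59.2 in sgSik1-3. Every Lkb1-deleted library lay below every other library, with 11.9 ± 4.05 CPM (n = 3) against 38.9 ± 5.78 in KT (n = 4), a log2 change of -1.71 (SE 0.54, adjusted p 0.16). Counts over the whole gene include exons outside a floxed part, so remaining Stk11 counts do not measure remaining function. Without sgSik1 replicate 1, which held 137 CPM, the same change of -1.71 passed with adjusted p 0.0312, as it did with only these 2 groups fitted (0.0374) and without a low-count filter (0.00799). In Sik-targeted libraries the Stk11 change against KT was 0.53 (SE 0.46, adjusted p 0.483), and -0.11 (adjusted p 0.849) without sgSik1 replicate 1.

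Sik1 (chromosome 17, 31844250 to 31855804, minus strand) stood at 38.2, 48.5, 48.0 and 59.6 CPM in KT, at 162, 214 and 149 in Lkb1-deleted, at 514, 112 and 148 in sgSik1 and at 105 and 266 in sgSik1-3 libraries. It rose by 2.24 (SE 0.45, adjusted p 0.0078) in Sik-targeted libraries against KT, and changed by 1.85 (SE 0.48, adjusted p 0.0852) with Lkb1 deletion. Indels made by Cas9 need not lower RNA, and Sik1 is itself induced by CREB. Without KT replicates 2 and 3 the Sik1 change of 2.20 in Sik-targeted libraries had adjusted p 0.122. The Sik1 change with Lkb1 deletion passed with DESeq2 or with only these 2 groups fitted (adjusted p 0.0133 in either), without a low-count filter (0.00145) and without sgSik1 replicate 1 (0.0167).

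Sik2 (chromosome 9, 50892801 to 51009073, minus strand) stood at 4.72, 10.4, 8.03 and 8.28 CPM in KT, 17.4, 19.5 and 31.8 in Lkb1-deleted, 28.1, 12.7 and 15.8 in sgSik1 and 17.5 and 18.1 in sgSik1-3 libraries. Its change was 1.22 (SE 0.34, adjusted p 0.0328) with Sik targeting and 1.53 (SE 0.38, adjusted p 0.0692) with Lkb1 deletion. The Sik2 change with Sik targeting kept its direction but did not pass when KT replicate 1, 2, 3 or 4 was left out (1.04, 1.39, 1.23 and 1.21, adjusted p 0.0825, 0.0561, 0.0891 and 0.0714). Nor did it pass without sgSik1 replicate 1 or 3 (1.01 and 1.27, adjusted p 0.0523 and 0.0518), without sgSik1-3 replicate 1 or 2 (1.23 and 1.22, adjusted p 0.0545 and 0.0609), or without KT replicates 2 and 3 together (1.48, adjusted p 0.152). The Sik2 change with Lkb1 deletion passed with DESeq2 (adjusted p 0.00886), without a low-count filter (0.0281) and without sgSik1 replicate 1 (0.0329).

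Sik3 (chromosome 9, 46012820 to 46224194, plus strand) stood at 31.2, 26.9, 39.3 and 46.7 CPM in KT, 38.5, 56.7 and 53.4 in Lkb1-deleted, 21.0, 20.9 and 9.17 in sgSik1 and 8.74 and 11.9 in sgSik1-3 libraries. It was lower in Sik-targeted libraries by a log2 change of -1.33 (SE 0.34, adjusted p 0.0209; 14.4 ± 6.16 CPM, n = 5, against 36.0 ± 8.79, n = 4). With Lkb1 deletion the Sik3 change was 0.46 (SE 0.38, adjusted p 0.669). The Sik3 change with Sik targeting kept its direction but did not pass without KT replicate 3 or 4 (-1.28 and -1.21, adjusted p 0.0601 and 0.0521) or sgSik1 replicate 3 (-1.20, adjusted p 0.0525). Nor did it pass without sgSik1-3 replicate 2 (-1.27, adjusted p 0.0535) or KT replicates 2 and 3 together (-1.46, adjusted p 0.119).

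**Figure D1:**
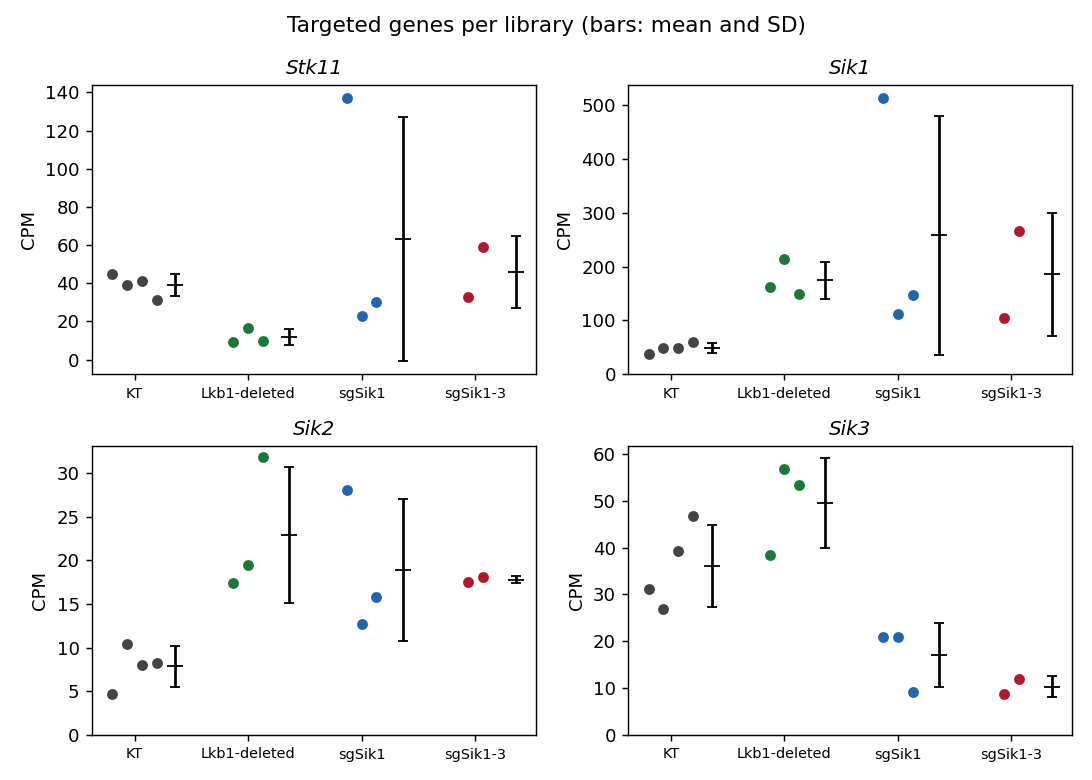
CPM of Stk11, Sik1, Sik2 and Sik3 in each of the 12 libraries, by group (KT, Lkb1-deleted, sgSik1, sgSik1-3). Bars are the group mean and SD.

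Several libraries stood apart. KT replicates 2 and 3 had counts in 23582 and 23747 genes, against 14283 to 16533 in the other 10 libraries, and in 1000 and 1066 olfactory or vomeronasal receptor genes against 14 to 58. Y-linked genes together held under 1 CPM of all counts in KT, in Lkb1-deleted replicate 1 and in all sgSik1 libraries, but 78.4 and 42.3 in Lkb1-deleted replicates 2 and 3 and 52.6 and 34.2 in sgSik1-3. Of 6 tested sex-linked genes, 3 passed in the comparison of Sik-targeted with KT libraries and 4 in that of sgSik1-3 with KT. The 4 most abundant transcripts, among them the ribosomal RNA precursor Rn45s and Malat1, held 18.4% of counts in KT replicate 1 and 74.2% in sgSik1 replicate 1, the lowest and highest shares. On the first dimension of the multidimensional scaling (39.7% of the variance), KT lay at -1.86 to -1.63 and Lkb1-deleted replicates 2 and 3 at -1.78 and -1.17. Lkb1-deleted replicate 1 lay at 1.98, beside sgSik1 (1.96, 0.24 and 1.81) and sgSik1-3 (1.99 and 1.92).

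**Figure D2:**
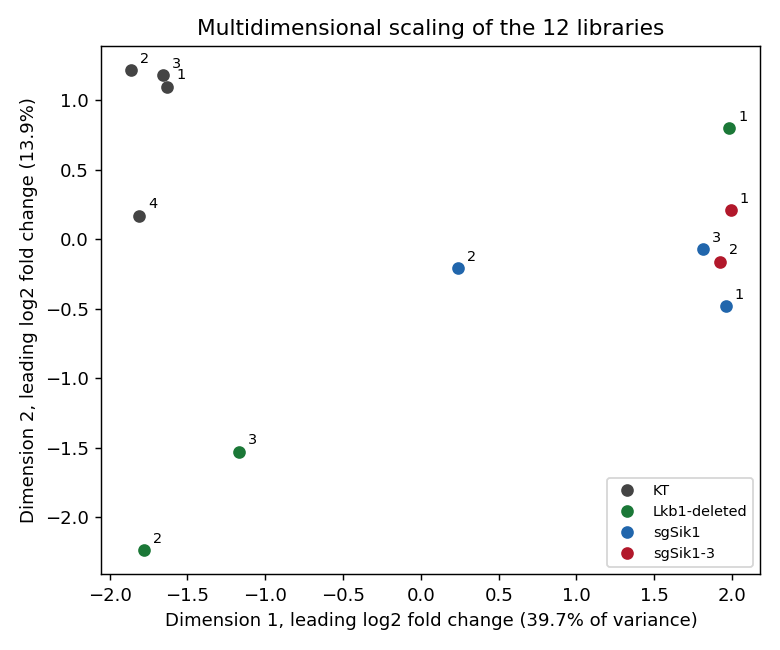
Multidimensional scaling of the 12 libraries on log2 CPM of tested genes, first dimension against second, coloured by group. Axis labels give the share of variance in percent.

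**Figure D3:**
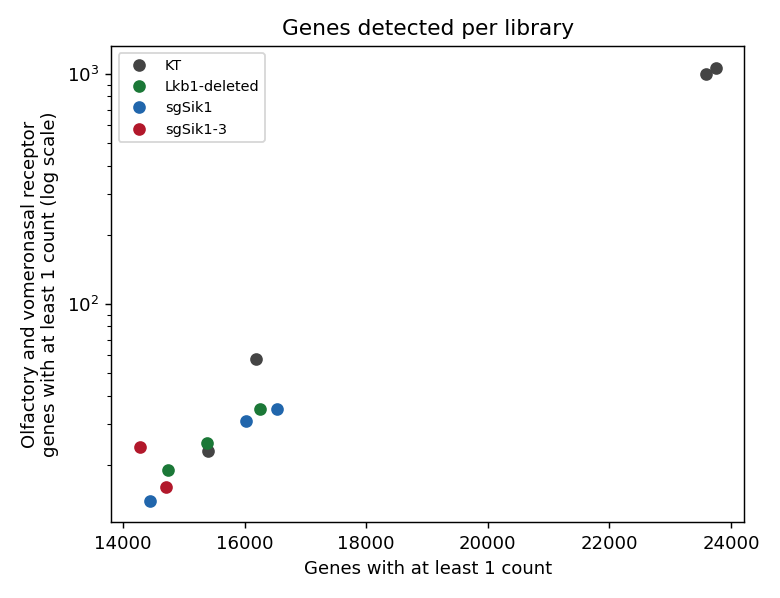
Genes with at least 1 count (horizontal axis) against olfactory and vomeronasal receptor genes with at least 1 count (vertical axis, log scale) in the 12 libraries. Each point is 1 library, coloured by group.

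With Lkb1 deletion Fosl1, which encodes an AP-1 subunit, rose 50.8-fold (log2 5.67, SE 0.96, adjusted p 0.0179; 17.0 ± 5.39 CPM, n = 3, against 0.317 ± 0.141, n = 4), and Stc1, a secreted glycoprotein induced by hypoxia, rose 43.0-fold (log2 5.43, SE 0.51, adjusted p 0.000182). Among members of the list of CREB and CRTC targets, Nr4a2 rose by 3.58 (SE 0.42, adjusted p 0.00128). Scgb1a1, the club-cell secretoglobin, fell by 6.34 (SE 1.16, adjusted p 0.0273; 12.5 ± 13.9 CPM against 1010 ± 1240), and Ctss, a cathepsin of antigen-presenting cells, fell by 6.40 (SE 0.72, adjusted p 0.00114).

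Of 13575 tested genes, 83 rose and 75 fell with Lkb1 deletion against KT, and 124 of the 158 changed by over 4-fold. Unadjusted p was under 0.05 in 1782 genes. The values of the 2 groups did not overlap in 156 of the 158 and in 1993 of all tested genes, where 5.71% would be so by chance. The count was 3 without KT replicates 2 and 3 together. It was 33, 13, 13 and 91 without KT replicate 1, 2, 3 or 4 (11 up and 22 down without replicate 1), and 82, 68 and 79 without Lkb1-deleted replicate 1, 2 or 3 (55 up and 27 down, 53 and 15, and 58 and 21). It was 240 and 99 without sgSik1 replicate 1 or 3, and 45 without sgSik1-3 replicate 2. With DESeq2 the count was 553 and with no low-count filter 846. With limma-voom 83 genes rose and 141 fell.

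Further large rises with Lkb1 deletion were Selp (P-selectin, 4.87, SE 0.84, adjusted p 0.0179), Pgm5 (4.05, SE 0.66, adjusted p 0.0145), the claudin Cldn2 (3.95, SE 0.85, adjusted p 0.0408) and the T-type calcium channel Cacna1h (3.92, SE 0.82, adjusted p 0.0377). Sfn (14-3-3 sigma) rose by 3.92 (SE 0.76, adjusted p 0.032), Fam43a by 3.77 (SE 0.83, adjusted p 0.0444) and the cytokine Il6 by 3.74 (SE 0.72, adjusted p 0.029). Resp18, a neuroendocrine granule protein, rose from 2 counts over the KT libraries to 47 (counting interval of the ratio 9.72 to 315, adjusted p 0.0274). It was the only called gene of the 3 tested members of the neuroendocrine list. The list's count was 0 to 1 when a library was left out and 0 without KT replicates 2 and 3.

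Large falls included genes of motile cilia. Dnahc5, an axonemal dynein, went from 319 counts over KT to 0 over Lkb1-deleted libraries, at least 67.3-fold (adjusted p 0.022). Dnahc8 went from 479 to 2 (interval 41.7 to 1260, adjusted p 0.0197) and Hydin from 296 to 2 (interval 25.7 to 777, adjusted p 0.0177). Cwh43 went from 200 counts to 0, at least 42.2-fold (adjusted p 0.029), Wdr52 from 390 to 1 (interval 44.1 to 9780, adjusted p 0.0184), Nov from 430 to 2 (interval 37.5 to 1130, adjusted p 0.0279) and the amino acid transporter Slc7a8 from 286 to 2 (interval 24.8 to 751, adjusted p 0.00739). Intervals and bounds from counts cover counting error only. Chi3l3 (-7.16, SE 1.13, adjusted p 0.0143) and Atp6v0d2 (-6.56, SE 1.12, adjusted p 0.0177), expressed by macrophages, fell too.

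Of 26 tested CREB and CRTC targets, 7 rose with Lkb1 deletion and 0 fell over all genes, and 14 rose adjusted over the list alone. Besides Nr4a2 these included the EGFR ligand Areg (2.01, SE 0.36, adjusted p 0.0197), Fosb (2.81, SE 0.52, adjusted p 0.0232) and Nr4a3 (3.36, SE 0.70, adjusted p 0.0377). The count lay between 1 and 9 when a library was left out and was 0 without KT replicates 2 and 3. The list's median change was 1.40, and 1.37 without KT replicates 2 and 3. Camera placed the list above other genes (adjusted p 4.8e-14, or 0.0195 with the correlation estimated). Of 18 MAPK output genes, 4 rose (11 over the list alone), with 0 to 7 when a library was left out and 0 without KT replicates 2 and 3. They were Fosl1, Dusp6 (2.19, SE 0.45, adjusted p 0.0365), Spry4 (1.83, SE 0.40, adjusted p 0.0408) and Phlda1 (2.03, SE 0.45, adjusted p 0.0414). Camera gave adjusted p 2.47e-12 for MAPK output, or 0.0277 with the correlation estimated, at a median of 1.29.

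Beside them moved the dissociation response, genes that handling of tissue at 37C switches on, a list which shares Fos, Fosb and Dusp1 with the CREB list and Ier3 and Egr1 with the MAPK list. Of its 20 tested members 7 rose (19 over the list alone), with 0 to 13 when a library was left out and 0 without KT replicates 2 and 3. Dnajb1, a heat-shock cochaperone, rose by 3.05 (SE 0.53, adjusted p 0.0179), Klf4 by 3.16 (SE 0.62, adjusted p 0.0322) and Atf3 by 2.14 (SE 0.46, adjusted p 0.0408). Its median was 1.97, with camera adjusted p 4.64e-23, or 0.0195 with the correlation estimated. Among 19 chemokine and NF-kB genes 3 rose (5 rose and 1 fell over the list alone), with 0 to 3 when a library was left out and 0 without KT replicates 2 and 3, among them Il6, Nfkbia (1.56, SE 0.36) and Tnfaip3 (1.72, SE 0.39), the last pair both at adjusted p 0.0468. Camera gave that list adjusted p 0.00224, but 0.147 with the correlation estimated, at a median of 0.60. Of 15 TGF-beta and matrix protease genes, 2 rose and 1 fell (5 and 2 over the list alone) at a median of 0.59 (camera adjusted p 0.0693), with 0 to 3 rises and 0 to 1 falls when a library was left out and 0 of either without KT replicates 2 and 3: Skil (1.76, SE 0.29, adjusted p 0.0143), Thbs1 (2.81, SE 0.63, adjusted p 0.0444) and Mmp12, from 260 counts to 1 (interval 29.3 to 6530, adjusted p 0.0377).

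With Lkb1 deletion 2 of 12 ciliated markers fell, Hydin and Dnahc5 (7 over the list alone), with 0 to 2 when a library was left out and 0 without KT replicates 2 and 3, at a median of -3.02 (camera adjusted p 4.42e-10, or 0.046 with the correlation estimated). Of 11 club markers 1 fell, Scgb1a1 (6 fell and 1 rose over the list alone), with 0 to 2 when a library was left out and 0 without KT replicates 2 and 3, at a median of -1.83 (camera adjusted p 8.16e-05, but 0.203 with the correlation estimated). None of 24 AT2 identity genes passed, at a median of -0.53 (camera adjusted p 0.011, but 0.509 estimated). None of 17 AT1 markers did over all genes, while 2 fell over the list alone (median -0.81, camera adjusted p 0.0215, but 0.444 estimated). The 19 epithelial genes had a median of 0.31 with 0 called (camera adjusted p 0.000441, but 0.399 estimated). Of 6 squamous and basal genes 1 rose, Sfn, with 0 to 1 when a library was left out and 0 without KT replicates 2 and 3. Their median was 1.02 (camera adjusted p 0.0701). Of 16 gastric and gut genes 0 passed over all genes, while 7 rose and 1 fell over the list alone, at a median of 1.96 (camera adjusted p 0.348). Their mean log2 CPM was 4.21 in Lkb1-deleted replicate 1 but 1.12 and 1.79 in replicates 2 and 3, against 1.64 to 2.31 in KT. Replicate 1 also lay furthest from KT in other lists. AT2 identity genes had means of 7.45, 8.52 and 8.72 in replicates 1 to 3, against 8.55 to 9.48 in KT. For AT1 markers these were 4.80, 5.93 and 6.09, against 6.03 to 7.07 in KT. For epithelial genes they were 6.43, 5.86 and 5.83, against 5.25 to 5.87 in KT.

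Among metabolic lists, 1 of 23 glycolysis and hypoxia genes rose with Lkb1 deletion, Pfkp (1.78, SE 0.41, adjusted p 0.0477). The count was 0 to 1 when a library was left out, 0 without KT replicates 2 and 3 and 2 over the list alone. The list's median was 0.71 (camera adjusted p 1.76e-05, but 0.308 with the correlation estimated). Its mean log2 CPM was 5.46 in Lkb1-deleted replicate 1 but 4.44 and 4.38 in replicates 2 and 3, against 3.98 to 4.33 in KT. None of 19 amino acid stress and serine synthesis genes passed, while 2 rose over the list alone (median 0.27, camera adjusted p 0.00997, but 0.316 estimated). None of 22 lipid and sterol synthesis genes passed (median -0.05, camera adjusted p 0.766; 1 fell over the list alone), and none of 26 oxidative phosphorylation genes (median -0.09, though camera pointed up with adjusted p 0.429). None of 26 cell cycle genes passed (median 0.13, adjusted p 0.243). Also with 0 called members and no camera call were LKB1 complex and substrate kinases (27 tested, median 0.24, adjusted p 0.348) and mesenchymal and EMT genes (14, median 0.02, adjusted p 0.512). So were YAP and TEAD targets (15, median 0.19, adjusted p 0.348) and chromatin and embryonic progression genes (10, median 0.54, adjusted p 0.525). Over the list alone, 2 mesenchymal genes rose, 3 YAP and TEAD targets rose and 1 fell, and 3 chromatin genes rose and 2 fell.

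With Lkb1 deletion 6 of 12 macrophage markers fell (11 over the list alone), with 2 to 6 when a library was left out and 1 without KT replicates 2 and 3. The chemokine Ccl6 fell by 6.16 (SE 0.86, adjusted p 0.00511) and the scavenger receptor Marco by 5.97 (SE 0.94, adjusted p 0.0143). The median was -4.62, also with a member at 0 counts set at its bound (camera adjusted p 5.61e-15, or 0.0277 with the correlation estimated). Of 8 pan-leukocyte markers 2 fell (5 fell and 1 rose over the list alone), with 0 to 3 when a library was left out and 0 without KT replicates 2 and 3: Itgb2 (-4.99, SE 1.02, adjusted p 0.0366) and Ptprc, from 206 counts to 1 (interval 23.1 to 5180, adjusted p 0.0408). That list's median was -2.82 (camera adjusted p 2.71e-05, or 0.0195 estimated). None of 13 MHC class I genes passed (median -0.55, camera adjusted p 0.0104, but 0.444 estimated), none of 7 MHC class II genes (median -0.77, adjusted p 0.115), and none of 21 interferon response genes (median -0.04, adjusted p 0.678; 1 fell over the list alone). None of 14 endothelial markers passed (median 1.2 and mean 1.05, though camera pointed down with adjusted p 0.718), and none of 16 fibroblast and pericyte markers (median -0.17, adjusted p 0.0619). Of the lists of neutrophil (2 tested), T and NK cell (2), B and plasma cell (1) and erythroid markers (1), 0 members passed over all genes, and 1 B-cell marker fell over its list alone. Lkb1-deleted replicates differed in the endothelial list (mean log2 CPM 0.38, 3.91 and 2.60, against 1.60 to 2.32 in KT) and the fibroblast list (0.92, 4.98 and 3.14, against 2.36 to 4.92). In MHC class I genes the mean was 3.55 in replicate 1 and 4.26 and 4.57 in replicates 2 and 3, against 4.66 to 5.21 in KT.

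With Sik targeting Tff1, a gastric trefoil peptide, rose by 9.19 (SE 1.76, adjusted p 0.0069; 668 ± 522 CPM, n = 5, against 1.15 in KT, n = 4), and Stc1 rose 96.9-fold (log2 6.60, SE 0.52, adjusted p 1.58e-05; 304 ± 103 CPM against 3.04 ± 1.39). Car9, the hypoxia-induced carbonic anhydrase, rose 31.0-fold (log2 4.95, SE 0.58, adjusted p 0.000377). Etv5, a transcription factor that maintains AT2 cells, fell by 2.11 (SE 0.36, adjusted p 0.00351), and Scgb1a1 fell by 5.36 (SE 0.88, adjusted p 0.00346).

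Of 13575 tested genes, 789 rose and 890 fell with Sik targeting against KT, and 1088 of the 1679 changed by over 4-fold. Unadjusted p was under 0.05 in 3867 genes. The groups did not overlap in 1352 of the 1679 and in 2187 of all tested genes, where 1.59% would be so by chance. The count was 98 without KT replicates 2 and 3 together. It was 633, 737 and 1088 without KT replicate 2, 3 or 4, 1010 without sgSik1 replicate 3 and 936 without sgSik1-3 replicate 2. With DESeq2 it was 2526 and with no low-count filter 3654 (1235 up and 2419 down).

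Among the largest rises with Sik targeting stood Dpcr1 (8.13, SE 1.52, adjusted p 0.00638), intestinal alkaline phosphatase Alpi (7.06, SE 1.65, adjusted p 0.0162), coagulation factor F5 (6.23, SE 1.51, adjusted p 0.0189) and the mucosal glycoprotein Dmbt1 (6.15, SE 1.41, adjusted p 0.0151). The protease genes Mcpt1 (7.91, SE 1.81, adjusted p 0.0148), Mcpt2 (7.06, SE 1.94, adjusted p 0.0309) and Mcpt8 (6.52, SE 1.59, adjusted p 0.0198), known from mast cells and basophils, rose as well. Fosl1 rose by 6.72 (SE 0.95, adjusted p 0.00162). Among the largest falls were Chi3l3 (-7.55, SE 0.92, adjusted p 0.00061), the integrin Itgax (-6.63, SE 1.01, adjusted p 0.00189), Gpnmb (-5.95, SE 0.92, adjusted p 0.00224), complement C7 (-5.85, SE 1.37, adjusted p 0.0158) and the elastic-fibre protein Mfap4 (-5.81, SE 1.31, adjusted p 0.0141). Over the KT and Sik-targeted libraries Marco went from 461 counts to 2 (interval 66.3 to 2000, adjusted p 0.000377), Plek from 475 to 2 (68.3 to 2060, adjusted p 0.00276), Nov from 430 to 2 (61.8 to 1860, adjusted p 0.00177), Hydin from 296 to 2 (42.4 to 1280, adjusted p 0.000986) and Pygo1 from 196 to 3 (23 to 334, adjusted p 0.00177).

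Of 24 AT2 identity genes 9 fell and 0 rose with Sik targeting (15 fell over the list alone), with 5 to 13 when a library was left out and 3 without KT replicates 2 and 3. Besides Etv5 these were the lung chemokine Cxcl15 (-3.43, SE 0.62, adjusted p 0.0046), the surfactant lipid enzyme Lpcat1 (-2.16, SE 0.44, adjusted p 0.00789) and the lamellar-body protein Lamp3 (-2.70, SE 0.57, adjusted p 0.00906), among others. The median was -1.18 (camera adjusted p 2.92e-07, but 0.175 with the correlation estimated). All 12 ciliated markers fell (7 to 12 when a library was left out, 2 without KT replicates 2 and 3), including Dnahc5 (-5.12, SE 0.92, adjusted p 0.00571) and the ciliogenesis factor Foxj1 (-4.00, SE 0.83, adjusted p 0.00848). Their median was -4.65 (camera adjusted p 1.83e-10, but 0.0822 estimated). Of 11 club markers 6 fell and 1, the airway mucin Muc5b, rose (7 and 2 over the list alone), with 4 to 7 falls and 0 to 1 rises when a library was left out and 3 falls without KT replicates 2 and 3, among them the carbonyl reductase Cbr2 (-5.50, SE 0.93, adjusted p 0.00411). Their median was -2.19 (camera adjusted p 0.0115, but 0.3 estimated).

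Of 16 gastric and gut genes 9 rose with Sik targeting and 0 fell (12 rose and 1 fell over the list alone), with 4 to 12 when a library was left out and 0 without KT replicates 2 and 3. They included the galectin Lgals4 (4.10, SE 0.64, adjusted p 0.0022), villin Vil1 (4.16, SE 0.76, adjusted p 0.00469) and the gastric protease Ctse (4.49, SE 1.01, adjusted p 0.0138). The list's median was 3.47 (camera adjusted p 7.92e-07, but 0.175 with the correlation estimated). Of 6 squamous and basal genes 3 rose (4 over the list alone), with 1 to 4 when a library was left out: Sfn (4.12, SE 0.74, adjusted p 0.00459), Sprr1a (2.76, SE 0.72, adjusted p 0.0246) and Krt14 (4.12, SE 1.13, adjusted p 0.0297). Their median was 3.16 (camera adjusted p 0.00517, but 0.127 estimated). Of 19 epithelial genes 5 rose (8 over the list alone), with 2 to 6 when a library was left out, namely Krt18 (2.02, SE 0.37, adjusted p 0.00475), Elf3 (2.36, SE 0.50, adjusted p 0.00883) and Krt19 (2.71, SE 0.61, adjusted p 0.0124) beside Krt8 and Esrp2, at a median of 0.95 (camera adjusted p 1.34e-06, but 0.175 estimated). Without KT replicates 2 and 3, 0 squamous and 0 epithelial genes passed.

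Of 17 AT1 markers 2 rose, Krt7 (2.13, SE 0.48, adjusted p 0.013) and Gprc5a (1.31, SE 0.34, adjusted p 0.0235), and 2 fell, Rtkn2 (-3.21, SE 0.71) and Cav1 (-2.56, SE 0.57), both at adjusted p 0.012 (4 and 4 over the list alone, 0 to 3 rises and 2 to 5 falls when a library was left out, 0 without KT replicates 2 and 3; median -0.31, camera adjusted p 0.963). Of 10 chromatin and embryonic progression genes 4 rose and 1 fell, over all genes and over the list alone, with 2 to 4 rises and 1 fall when a library was left out and 1 fall left without KT replicates 2 and 3. Plac8 rose by 5.60 (SE 1.00, adjusted p 0.00459), Sox9 by 4.89 (SE 0.92, adjusted p 0.00652) and Hmga1 by 2.24 (SE 0.61, adjusted p 0.0283), with Hmga2 as the other rise, while the receptor tyrosine kinase Ros1 fell by 3.59 (SE 0.40, adjusted p 0.000377). That list's median was 1.09 (camera adjusted p 0.126). Of 14 mesenchymal and EMT genes 2 rose and 1 fell (2 and 7 over the list alone; median -1.49, camera adjusted p 0.531), with 2 rises and 0 to 5 falls when a library was left out and 1 rise left without KT replicates 2 and 3. Integrin Itgb3 rose by 3.76 (SE 0.58, adjusted p 0.00207) and the membrane protease Mmp14 by 2.28 (SE 0.41, adjusted p 0.00459), while the gelatinase Mmp2 fell by 3.61 (SE 1.1, adjusted p 0.0447). Of the 3 neuroendocrine genes 1 rose, Resp18, and 0 without KT replicates 2 and 3.

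Of 23 glycolysis and hypoxia genes 16 rose with Sik targeting (18 over the list alone), with 7 to 18 when a library was left out and 2 without KT replicates 2 and 3. Besides Car9 they included phosphofructokinase Pfkp (2.29, SE 0.38, adjusted p 0.00306), Ndrg1 (3.25, SE 0.56, adjusted p 0.00367) and pyruvate kinase Pkm (1.93, SE 0.41, adjusted p 0.0101). The median was 1.51 (camera adjusted p 5.12e-13, but 0.0975 with the correlation estimated). Of 22 lipid and sterol synthesis genes 5 fell (5 fell and 1 rose over the list alone), with 2 to 5 when a library was left out and 0 without KT replicates 2 and 3, namely acetyl-CoA carboxylase Acaca (-1.66, SE 0.36, adjusted p 0.0102), the desaturases Fads1 (-2.17, SE 0.49, adjusted p 0.0122) and Scd1 (-1.92, SE 0.51, adjusted p 0.0251), and Scd2 and Elovl1, with a list median of -0.14 (camera adjusted p 0.302). Of 26 cell cycle genes 4 rose (14 over the list alone), with 1 to 7 when a library was left out and 0 without KT replicates 2 and 3: Mki67 (2.01, SE 0.44, adjusted p 0.0115), Top2a (2.03, SE 0.55, adjusted p 0.0266), Foxm1 (1.41, SE 0.38, adjusted p 0.0279) and Plk1 (2.81, SE 0.88, adjusted p 0.048). The cell cycle median was 1.36 (camera adjusted p 3.02e-07, but 0.176 estimated). Of 19 amino acid stress and serine synthesis genes 1 rose, Atf4 (0.94, SE 0.29, adjusted p 0.0487), with 0 to 3 when a library was left out, 0 without KT replicates 2 and 3, 0 over the list alone and a median of 0.27 (camera adjusted p 0.163). None of 26 oxidative phosphorylation genes passed (median 0.16, camera adjusted p 0.119).

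With Sik targeting 13 of 26 CREB and CRTC targets rose (15 over the list alone), with 7 to 13 when a library was left out and 3 without KT replicates 2 and 3. They included Nr4a2 (3.01, SE 0.39, adjusted p 0.000805), the cAMP phosphodiesterase Pde4b (2.65, SE 0.39, adjusted p 0.00176), Areg (2.20, SE 0.34, adjusted p 0.00207) and Nr4a1 (2.86, SE 0.56, adjusted p 0.0068), at a median of 1.52 (camera adjusted p 3.94e-09, but 0.0822 with the correlation estimated). Of 18 MAPK output genes 11 rose and 2 fell, Spry1 and Etv1 (12 and 2 over the list alone), with 8 to 12 rises when a library was left out and 0 without KT replicates 2 and 3. Dusp6 rose by 2.56 (SE 0.42, adjusted p 0.00281), Phlda1 by 2.50 (SE 0.42, adjusted p 0.00335) and Ier3 by 2.54 (SE 0.46, adjusted p 0.00459). The MAPK median was 2.03 (camera adjusted p 2.07e-07, but 0.0996 estimated). Of the 20 dissociation response genes beside them 10 rose (14 over the list alone), with 5 to 12 when a library was left out and 0 without KT replicates 2 and 3. These included Klf4 (2.63, SE 0.58, adjusted p 0.0113), and Dnajb1 (2.18, SE 0.48) and Dusp1 (1.96, SE 0.43), both at adjusted p 0.0116. The dissociation median was 1.78 (camera adjusted p 2.59e-09, but 0.0975 estimated).

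Of 15 YAP and TEAD targets 4 rose and 1 fell (6 and 1 over the list alone), with 1 to 6 rises when a library was left out and 0 without KT replicates 2 and 3, namely tissue factor F3 (2.85, SE 0.49, adjusted p 0.00347) and the matricellular Cyr61 (1.62, SE 0.47, adjusted p 0.0377), beside Crim1 and Ptpn14, with a fall of Axl, at a median of 0.73 (camera adjusted p 0.00343, but 0.175 with the correlation estimated). Of 15 TGF-beta and matrix protease genes 7 rose and 2 fell (the same over the list alone), with 3 to 7 rises and 1 to 3 falls when a library was left out and 1 rise left without KT replicates 2 and 3. The urokinase receptor Plaur rose by 3.44 (SE 0.48, adjusted p 0.00123), while Mmp12 and Ltbp2 fell. The median was 0.31 and the mean -0.02, while camera pointed up (adjusted p 0.0363, but 0.3 estimated). Of 19 chemokine and NF-kB genes 5 rose and 1 fell (6 and 2 over the list alone), with 3 to 6 rises when a library was left out and 0 without KT replicates 2 and 3: Lif rose by 3.63 (SE 0.60, adjusted p 0.00282), as did Tnfaip3, Nfkbia, Tnf and Il33, and Csf1 fell by 3.18 (SE 0.82, adjusted p 0.0229). Their median was 0.50 (camera adjusted p 0.00743, but 0.175 estimated). Of 27 LKB1 complex and substrate kinase genes 1 rose and 2 fell, over all genes and over the list alone, with 0 to 1 rises and 2 to 3 falls when a library was left out and 0 without KT replicates 2 and 3: Hdac4 (1.53, SE 0.47, adjusted p 0.0437), the AMPK subunit Prkaa2 (-3.08, SE 0.60, adjusted p 0.00669) and Hdac9 (-3.32, SE 0.80, adjusted p 0.0165). That list's median was -0.18 (camera adjusted p 0.658).

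With Sik targeting 6 of 7 MHC class II genes fell (7 over the list alone), with 0 to 6 when a library was left out and 0 without KT replicates 2 and 3. They included H2-Aa (-2.36, SE 0.65, adjusted p 0.0295) and H2-DMb1 (-2.21, SE 0.60, adjusted p 0.0274), at a median of -2.21 (camera adjusted p 6.06e-05, but 0.2 with the correlation estimated). Of 13 MHC class I genes 1 fell, the transactivator Nlrc5 (-3.56, SE 0.95, adjusted p 0.0262), with 0 to 7 when a library was left out and 0 without KT replicates 2 and 3, at a median of -0.97 (camera adjusted p 0.000831, but 0.254 estimated). Of 12 macrophage markers 10 fell (11 over the list alone), with 10 whichever library was left out and 3 without KT replicates 2 and 3. Ccl6 fell by 5.72 (SE 0.67, adjusted p 0.000377) and the phagocyte oxidase subunit Cybb by 5.74 (SE 0.91, adjusted p 0.00239). The macrophage median was -5.28, also with a member at 0 counts set at its bound (camera adjusted p 2.27e-11, but 0.0822 estimated). Of 8 pan-leukocyte markers 5 fell (5 fell and 2 rose over the list alone), with 1 to 5 falls and 0 to 1 rises when a library was left out and 1 fall without KT replicates 2 and 3, namely Laptm5 (-5.04, SE 0.81, adjusted p 0.00248), Ptprc (-3.46, SE 0.88, adjusted p 0.0218), Ikzf1, Itgb2 and Arhgdib. Their median was -2.26 (camera adjusted p 0.0186, but 0.127 estimated).

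Of 16 fibroblast and pericyte markers 7 fell and 1, Tagln, rose (9 and 1 over the list alone), with 2 to 10 falls when a library was left out and 0 without KT replicates 2 and 3, including Inmt (-5.10, SE 1.12, adjusted p 0.0117) and collagen Col3a1 (-4.19, SE 1.01, adjusted p 0.0186). Their median was -2.59 (camera adjusted p 0.00912, but 0.521 with the correlation estimated). Of 14 endothelial markers 1 fell, Esam (-1.64, SE 0.49, adjusted p 0.0417), with 0 to 3 when a library was left out and 0 without KT replicates 2 and 3, at a median of -0.45 (camera adjusted p 0.232; 0 over the list alone). Members of lists named here without a value were added, after their values were seen, to complete counts of 5 or fewer. None of 21 interferon response genes passed (median 0.01, though camera pointed down with adjusted p 0.943), nor any neutrophil, T and NK cell, B and plasma cell or erythroid marker.

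**Figure D4:**
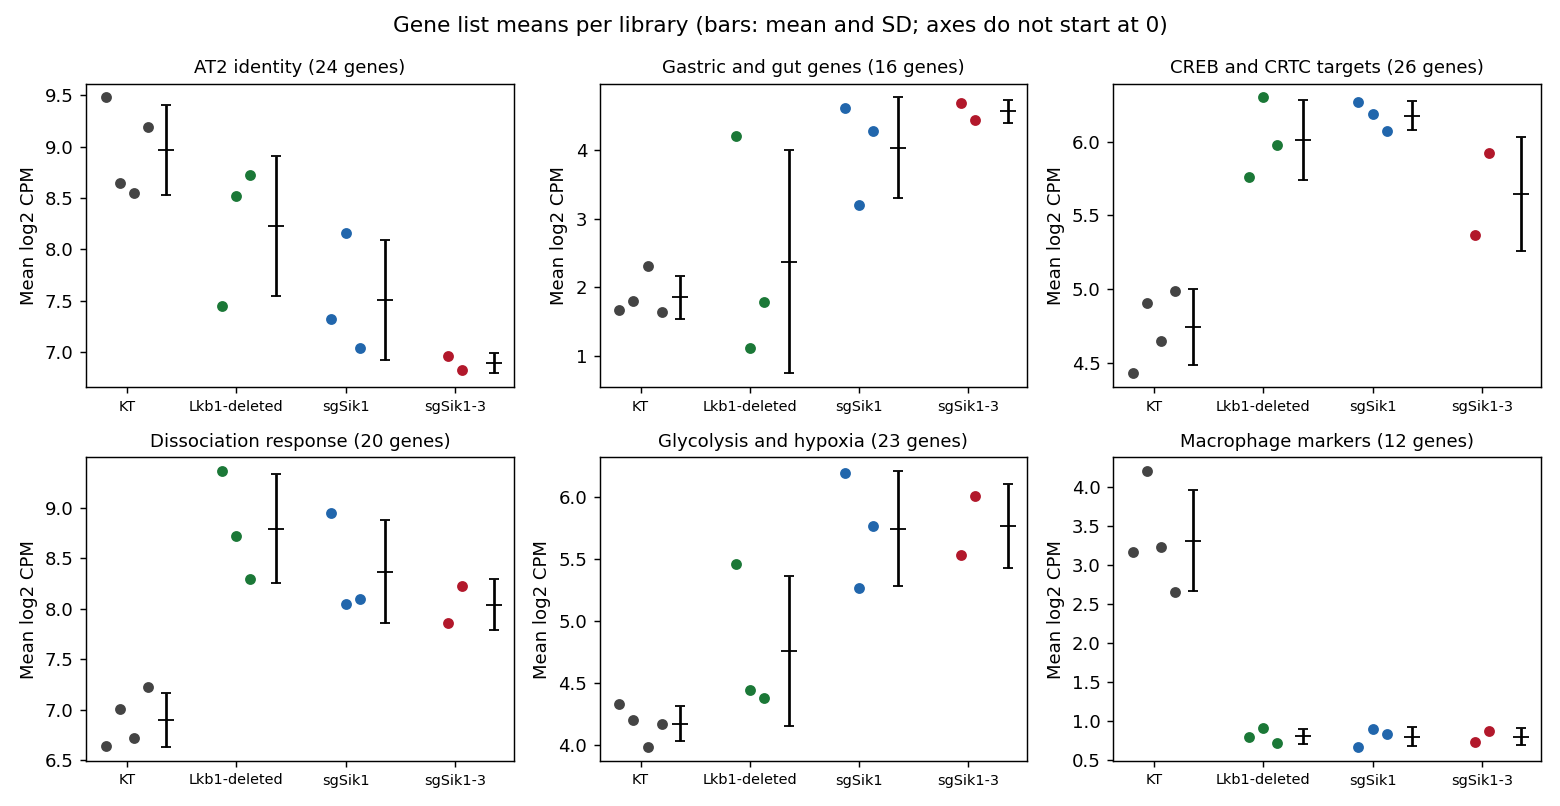
Mean log2 CPM of 6 gene lists (AT2 identity, gastric and gut, CREB and CRTC, dissociation, glycolysis and hypoxia, macrophage) in each of the 12 libraries, by group. Bars are the group mean and SD, and vertical axes do not start at 0.

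Of the genes called with Lkb1 deletion, most were also called with Sik targeting, against the same KT libraries. Fosl1, Stc1, Resp18, Selp and Sfn rose in both comparisons against KT, and Chi3l3, Nov, Hydin, Marco and Ccl6 fell in both. In all, 65 genes rose in both, 62 fell in both and 0 moved in opposite directions. The shared genes were 78.3% of those raised and 82.7% of those lowered by Lkb1 deletion. Fosl1 went from 12 counts over the KT libraries to 415 over the Lkb1-deleted ones, and Sfn changed by 3.92 (SE 0.76) with Lkb1 deletion and 4.12 (SE 0.74) with Sik targeting.

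Independent lists of these sizes would share 4.82 rises and 4.92 falls. Because both comparisons use the same KT libraries, unchanged groups were also simulated 20 times, and in these 0 genes were called with Lkb1 deletion and 0 to 1 with Sik targeting, so that 0 could be shared and only the correlation and covariance of the simulations bear on the result. The fold changes of all genes correlated at 0.667 with 73.5% of equal sign, against 0.478 (0.461 to 0.496) and 66.1% in the simulations. Their covariance was 1.11 against 0.2 (0.192 to 0.208), a difference of 0.91. With the KT libraries split 2 and 2 between the comparisons, in 6 ways, the correlation averaged 0.532 (0.43 to 0.632) and the covariance 0.958 (0.824 to 1.08), while 0 to 1 genes were called with Lkb1 deletion and 0 to 1 were shared. The correlation fell to 0.398 without Lkb1-deleted replicate 1. The simulated range of 0.461 to 0.496 holds for all 12 libraries and depends on group sizes. No simulation was run without that replicate, so whether 0.398 lies below the level of unchanged groups is open.

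The 127 shared genes became 2 without KT replicates 2 and 3 together. They became 32, 12, 12 and 81 without KT replicate 1, 2, 3 or 4, and 62, 65 and 66 without Lkb1-deleted replicate 1, 2 or 3. They became 80 without sgSik1 replicate 3 and 41 without sgSik1-3 replicate 2. DESeq2 shared 420, limma-voom 191 (63 rises and 128 falls), and the fit without a low-count filter 680.

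Compared directly, Lkb1-deleted libraries held more of the matrix protein Thbs1 (3.18, SE 0.59, adjusted p 0.0374; 948 CPM, n = 3, against 104 in Sik-targeted libraries, n = 5) and of Ros1 (2.29, SE 0.41, adjusted p 0.0321). Car9 was lower by a log2 change of -6.40 (SE 0.73, adjusted p 0.00274; 0.736 CPM against 59.0), and so was the chromatin protein Hmga2 (-4.26, SE 0.77, adjusted p 0.0321). Thbs3 (2.87, SE 0.42, adjusted p 0.00911), the glutamate transporter Slc1a3 (3.66, SE 0.68, adjusted p 0.0374), the potassium channel Kcnj13 (3.47, SE 0.59, adjusted p 0.0267), Bex2 (3.38, SE 0.66, adjusted p 0.0495) and the MAPK feedback gene Spry1 (1.63, SE 0.28, adjusted p 0.0267) were also higher with Lkb1 deleted. The sodium channel Scn8a (-6.36, SE 1.06, adjusted p 0.0267) and the desmosomal Pkp1 (-5.99, SE 0.93, adjusted p 0.0182) were lower. Cwh43 had 0 counts over Lkb1-deleted and 284 over Sik-targeted libraries, at least 57.3-fold (adjusted p 0.0296), and Muc3 had 3 against 495 (interval 34.0 to 486, adjusted p 0.0267).

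In this direct comparison 14 genes were higher and 16 lower of 13575, with unadjusted p under 0.05 in 1723, and 29 of the 30 differed by over 4-fold. The groups did not overlap in 29 of the 30 and in 730 of all tested genes, where 3.57% would be so by chance. The count moved to 740 without Lkb1-deleted replicate 1, 7 and 2 without replicates 2 or 3 of that group, and 13, 270 and 12 without sgSik1 replicate 1, 2 or 3. It was 12 and 9 without sgSik1-3 replicate 1 or 2, 9, 19 and 18 without KT replicate 2, 3 or 4, and 9 without KT replicates 2 and 3 together. It was 0 when only these 2 groups were fitted, 345 with DESeq2 and 698 with no low-count filter.

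Among lists, 1 chromatin and embryonic progression gene was higher (Ros1) and 1 lower (Hmga2), and 1 glycolysis gene (Car9), 1 MAPK gene (Spry1) and 1 TGF-beta gene (Thbs1) differed, while the other lists had 0 called members. These zeros hung on single libraries: with 1 library left out, up to 10 fibroblast, 7 endothelial, 6 AT2 and 4 lipid genes were higher, and up to 9 gastric and 5 cell cycle genes lower. In these fits 1 to 6 glycolysis and 0 to 4 chromatin genes were lower, and 0 to 1 chromatin, 0 to 2 MAPK and 0 to 2 TGF-beta genes higher. Without KT replicates 2 and 3 only the glycolysis gene passed among them. Camera placed AT2 identity (adjusted p 8.11e-06), MHC class II (6.45e-05) and the dissociation response (0.00121) higher with Lkb1 deleted, each with adjusted p 0.438 when the correlation was estimated. It placed gastric and gut genes (1.73e-09), glycolysis and hypoxia (4.1e-08), cell cycle (2.64e-07), AT1 markers (0.00324) and YAP and TEAD targets (0.00919) lower, each again with adjusted p 0.438 when the correlation was estimated. Epithelial genes were lower too (0.00919, but adjusted p 0.645 estimated). In the AT2, MHC class II, gastric, glycolysis and epithelial lists, Lkb1-deleted replicate 1 lay within the Sik-targeted range, and replicates 2 and 3 outside it. For AT2 identity the mean log2 CPM was 7.45, 8.52 and 8.72 in replicates 1 to 3, against 6.82 to 8.16 in Sik-targeted libraries. For gastric genes it was 4.21, 1.12 and 1.79, against 3.21 to 4.69. In the dissociation and AT1 lists replicate 1 lay outside that range. The direction by camera differed from that of the median or mean for CREB and CRTC targets (median -0.06, mean -0.07, camera up, adjusted p 0.676), chemokine and NF-kB genes (0.07, -0.22, down, adjusted p 0.921) and TGF-beta genes (-0.39, 0.20, down, adjusted p 0.303).

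In sgSik1 libraries against KT Tff1 rose by 9.28 (SE 1.94, adjusted p 0.0252), Dpcr1 by 7.59 (SE 1.61, adjusted p 0.0261), Fosl1 by 7.20 (SE 0.90, adjusted p 0.00119) and Stc1 by 6.63 (SE 0.55, adjusted p 2.61e-05). In sgSik1-3 libraries, against the same KT libraries, Tff1 rose by 9.10 (SE 1.97, adjusted p 0.0331), Dpcr1 by 8.72 (SE 1.71, adjusted p 0.0241), Stc1 by 6.61 (SE 0.56, adjusted p 4e-05) and Plac8 by 6.48 (SE 0.96, adjusted p 0.0044). Sik1 rose by 2.43 (SE 0.49, adjusted p 0.0139) in sgSik1 and changed by 1.95 (SE 0.52, adjusted p 0.0537) in sgSik1-3. The Sik3 change was -1.06 (SE 0.38, adjusted p 0.121) in sgSik1 and -1.78 (SE 0.47, adjusted p 0.0507) in sgSik1-3.

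Of 15303 genes, 415 rose and 173 fell in sgSik1 (n = 3) against KT (n = 4), with unadjusted p under 0.05 in 3729. The groups did not overlap in 565 of the 588 and in 2889 of all tested genes, where 5.71% would be so by chance. Pbp2 went from 2 counts to 432 (interval 76.1 to 2290, adjusted p 0.0345), Marco from 461 to 1 (64.3 to 14300, adjusted p 0.00223), Plek from 475 to 1 (66.3 to 14700, adjusted p 0.0139), Hydin from 296 to 1 (41.2 to 9160, adjusted p 0.00476) and Nov from 430 to 2 (46.2 to 1390, adjusted p 0.0134), while Chi3l3 fell by 7.34 (SE 1.2, adjusted p 0.00843). The count was 12 without KT replicates 2 and 3, 265, 148, 198 and 281 without KT replicate 1, 2, 3 or 4, and 1296 without Lkb1-deleted replicate 1. It was 138, 1161 and 338 without sgSik1 replicate 1, 2 or 3. DESeq2 called 1445 (788 up and 657 down), the fit without a filter 1783 (963 and 820), and the fit of these 2 groups alone 954 (523 and 431). With limma-voom 383 rose and 458 fell.

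In sgSik1-3 (n = 2) against KT, 267 genes rose and 176 fell, with unadjusted p under 0.05 in 3133. The groups did not overlap in 443 of the 443 and in 5476 of all tested genes, where 13.3% would be so by chance. Arl14 went from 3 counts to 75 (interval 31.2 to 469, adjusted p 0.0209). With 0 counts in sgSik1-3, Shank2 fell at least 44.3-fold (adjusted p 0.00703), Ccdc108 at least 39.3-fold (0.0488), Nov at least 37.9-fold (0.0316), the osteoclast and macrophage cathepsin Ctsk at least 35.3-fold (0.0171) and Wdr52 at least 34.3-fold (0.019). The count was 42 without KT replicates 2 and 3, 179, 141, 161 and 201 without KT replicate 1, 2, 3 or 4, and 1140 without Lkb1-deleted replicate 1. It was 729 and 667 without sgSik1 replicate 1 or 2, and 37 and 56 without sgSik1-3 replicate 1 or 2, each leaving 1 library whose spread is taken from the other groups. The balance turned to falls with DESeq2, which called 1264 (561 up and 703 down), in the fit without a filter, 1440 (701 and 739), and in the fit of these 2 groups alone, 1938 (946 and 992).

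Between sgSik1-3 and sgSik1 directly, edgeR called 0 of 15303 genes, with unadjusted p under 0.05 in 528 and no overlap of the groups in 2286, where 20% would be so by chance. DESeq2 called 6 and limma-voom 0, and without a low-count filter edgeR called 44. Sik1 differed by -0.48 (SE 0.58), Sik2 by -0.08 (SE 0.48) and Sik3 by -0.71 (SE 0.46), each with adjusted p 1. With 2 and 3 libraries, a count of 0 does not show that the groups are alike. This comparison, like that of sgSik1-3 with KT, sets libraries with Y-linked counts against libraries without, so sex and guide cannot be told apart in either. Lkb1-deleted replicates 2 and 3 also carried Y-linked counts, unlike the KT libraries. Sex is therefore partly mixed with genotype in the comparisons of Lkb1 deletion and of Sik targeting with KT too.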

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

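Chosen only after the result was seen were the Sik3 tests of an effect downstream of the Lkb1 pathway and of targeting of Sik3 itself, the fits without KT replicates 2 and 3, and the fits without the 4 most abundant transcripts. The reading of the test of genes near Stk11 was also changed after its value was seen.

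KT replicates 2 and 3 had counts in 23582 and 23747 genes, more than any other library. Deeper sequencing is spoken against by thinning all libraries to 2151939 counts, after which the lower of the pair still had 1.35 times the genes of the highest other library (10 draws). Of 3360 genes seen in both libraries and in none of the other 10, 713 were olfactory or vomeronasal receptor genes and 5 were leukocyte list members, a ratio of 143, but the lists hold 1435 and 58 genes and leukocyte genes seen elsewhere are left out, so this ratio does not exclude leukocytes in the sort. Reads from across the genome, such as DNA or unspliced RNA carried into the amplification, would put counts in silent receptor genes. These had a count for 1000 of 1435 in the lower of the pair and 58 in the highest other library, 17.2 times, which is consistent with that explanation but does not tell DNA from RNA.

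Sik3 was low in the sgSik1 libraries, whose title names only Sik1. An effect downstream of losing the pathway would lower Sik3 with Lkb1 deletion as well, but that change was 0.46 (SE 0.38), against -0.53 for an effect of 50% of the sgSik1 change, and the test leaves it open; Lkb1-deleted and Sik-targeted libraries differed in Sik3 by 1.79 (SE 0.36, adjusted p 0.0544, and 0.000553 with DESeq2, 0.0417 with limma-voom, 0.0322 with 4 title groups, 0.0455 without the 4 most abundant transcripts, but 0.179 with only these groups fitted and 0.236 without Lkb1-deleted replicate 2). Scaling by abundant transcripts would shrink the sgSik1 change of -1.06 (adjusted p 0.121), yet it was -1.11 with median-ratio size factors (adjusted p 0.113) and -1.08 without the 4 most abundant transcripts (adjusted p 0.117), and over all Sik-targeted libraries it stayed at -1.35 (adjusted p 0.0199) and -1.33 (adjusted p 0.0202); as the sgSik1 change passed in none of these fits, scaling is not excluded for sgSik1 alone. If Sik3 was also targeted, it might be low in each sgSik1 library, and 3 of 3 lay below every KT and Lkb1-deleted library; indels need not lower RNA, so this cannot settle it.

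Macrophage genes were lower in Lkb1-deleted and Sik-targeted libraries than in KT, although the sort excluded CD45 and F4/80. Macrophages in the KT sorts would carry general leukocyte genes with them, and the pan-leukocyte list had median changes of -2.82 and -2.26, which is consistent with that explanation. KT held 4.32 CPM of Ptprc, which encodes CD45. That only KT replicates 2 and 3 carry the excess is spoken against by the macrophage medians without them, -3.98 and -4.74, which kept 86% and 89.8% of the full values. A lower expression of these genes by the cancer cells themselves was not tested.

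Values of single libraries far from the rest of their group numbered 12 among 120 value sets tested, where about 1 in 20, or 6, is expected by chance. In KT these were Selp in replicate 3 (2.17 CPM against 0.157 to 0.298), Pgm5 in replicate 4 (6.37 against 1.45 to 1.89), Il6 in replicate 1 (0.472 against 1.45 to 1.56), Dnahc5 in replicate 4 (4.03 against 8.83 to 9.83), Pygo1 in replicate 4 (10.2 against 4.25 to 4.77), Bex2 in replicate 1 (47.8 against 12.3 to 15.5) and Pbp2 in replicate 3 (0.161 against 0). In Sik-targeted libraries they were Fam43a in sgSik1 replicate 1 (437 against 61.4 to 87.6), Wdr52 in sgSik1 replicate 2 (0.854 against 0 to 0.0546), Marco in sgSik1-3 replicate 1 (0.236 against 0 to 0.0546), Pkp1 in sgSik1 replicate 2 (21.6 against 81.4 to 102) and Ccdc108 in sgSik1 replicate 2 (2.70 against 0 to 0.284). Only KT and Sik-targeted libraries were tested in this way, so no Lkb1-deleted library could be flagged. The flagged values of Marco and Pbp2 lay under the floor of 3 counts (0.709 CPM in sgSik1-3 replicate 1 and 0.241 CPM in KT replicate 3). A difference between the effects of Lkb1 deletion and Sik targeting was tested directly, and 30 genes differed.

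Regrouping the libraries set the real counts beside those of other splits. For Lkb1 deletion against KT, 1 of 35 splits, the real one, reached 158 genes, and the highest other called 1. That share of 0.0286 is the smallest that 35 splits can give. If the genotypes differ, splits that mix them have a wider spread within groups, so low counts in them are partly built in. For sgSik1 against KT, 1 of 35 reached 588, and the highest other called 0. For Sik targeting against KT the 100 splits were the real one and a random draw of the others. Of these 1 reached 1679, and the highest other, which puts sgSik1 replicate 2 with the KT libraries, called 1550. For Lkb1 deletion against Sik targeting, 3 of 56 splits reached 30 genes, so chance was not excluded there. The highest other called 962 by setting Lkb1-deleted replicates 2 and 3 with sgSik1 replicate 2 against the rest, many times the real count, which points to structure among the libraries other than the genotype.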

How the results depend on the processing

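Under every setting, 0 of 187 called gene results changed direction. Of these, 182 of 182 stayed called with DESeq2, 185 of 187 with median-ratio size factors, 160 with limma-voom, 186 without a low-count filter, 179 of 185 with a stricter filter, 160 with only the groups compared, 155 of 166 with 4 title groups, and 99 (without KT replicate 2) to 181 (without sgSik1 replicate 2) with 1 library left out. Totals under 187 leave out results without a value in that setting. The 187 results had passed in these same libraries, and many were picked as the largest changes without overlap between the groups. This pick left little room for a reversal, so the lack of reversals does not measure robustness. Among uncalled results 108 flipped sign without passing. Of 42 list calls, 42 stayed with median-ratio size factors or the stricter filter, 37 without a filter, 24 with fry, 6 with the estimated correlation, and 34 (without Lkb1-deleted replicate 1) to 42 with a library left out.

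Counts are given in the order Lkb1 deletion against KT, Sik targeting against KT, Lkb1 deletion against Sik targeting, sgSik1 against KT, sgSik1-3 against KT, sgSik1-3 against sgSik1, and genes shared by the first pair. They were 158, 1679, 30, 588, 443, 0 and 127 as reported. With DESeq2 they were 553, 2526, 345, 1445, 1264, 6 and 420. Without a low-count filter they were 846, 3654, 698, 1783, 1440, 44 and 680. With limma-voom the shared count was 191. With only the groups compared the third to sixth counts were 0, 954, 1938 and 2. With 4 title groups the first was 101 and the shared count 83. Median-ratio size factors and the stricter filter moved no count by over 1.5 times. With 1 library left out the counts ranged over 13 to 240, 633 to 2251, 2 to 740, 138 to 1296, 37 to 1140, 0 to 4, and 12 to 173. A fit without 1 of the sgSik1-3 libraries leaves 1, which is assumed to vary like the other groups. The cause was not tested. Leaving out a library also raised counts, as from 30 to 740 for Lkb1 deletion against Sik targeting without Lkb1-deleted replicate 1. Less power alone does not account for such rises. Leaving out any 1 KT library lowered the counts against KT, from 158 to between 13 and 91 for Lkb1 deletion. For Sik targeting the count went from 1679 to between 633 and 1123. For these falls less power was not told apart from other causes. Without a filter 113 uncalled results of named genes passed as well, so the extra calls were not all in the added genes. The added genes also enter the scaling, the estimate of the spread and the adjustment in that fit.

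The fits without KT replicates 2 and 3 and without the 4 most abundant transcripts were chosen after seeing the data. Without KT replicates 2 and 3 the counts were 3, 98, 9, 12, 42, 0 and 2, and 34 of 187 gene results and 40 of 42 list calls stayed. Without the 4 transcripts 187 of 187 and 42 of 42 stayed. The fit without KT replicates 2 and 3 has fewer KT libraries, so fewer calls there need not mean smaller changes. With Sik targeting against KT, the list median went from 3.47 to 3.70 for gastric and gut genes without that pair. It went from 2.03 to 1.94 for MAPK output and from -2.21 to -2.81 for MHC class II. For epithelial genes it shrank from 0.95 to 0.61, and other lists moved either way. The correlation of fold changes moved from 0.667 to 0.785 without a low-count filter and to 0.398 without Lkb1-deleted replicate 1, and stayed within the spread otherwise.

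In 3 cases a list that was not called turned direction and passed. Oxidative phosphorylation did so for Lkb1 deletion against KT without KT replicates 2 and 3 (adjusted p 0.0185). Endothelial markers did so for Lkb1 deletion against KT without Lkb1-deleted replicate 1 (adjusted p 2.82e-08, with 2.82e-08 to 0.894 over all libraries left out), and for Lkb1 deletion against Sik targeting without Lkb1-deleted replicate 2 (adjusted p 0.0184, with 1.33e-09 to 0.689 over all libraries left out). The cause was not tested.

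With the replicate number as a block the counts were 49, 1050, 10, 254, 126, 0 and 43, and 129 of 187 gene results and 39 of 42 list calls stayed. Among the targets, Sik2 and Sik3 no longer passed with the block for Sik targeting against KT (adjusted p 0.0952 and 0.0899). The samples share only a number: of 15 pairs of libraries with the same number, 6 correlated over 0.1 after removing group means (-0.335 to 0.249), and 3 of 12 libraries correlated best with their own number. The sgSik1 comparisons with 3 genotype groups have no value, because those groups do not separate sgSik1 from sgSik1-3.

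Depth limits what can be seen to fall: in single libraries 3 counts corresponded to 0.164 CPM in sgSik1 replicate 3, the deepest by effective size, and to 0.853 CPM in sgSik1 replicate 1, the shallowest.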

Other observations

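Some genes were looked at only after their values were seen. Lkb1-deleted replicate 1 carried the gut and mast-cell protease genes of the Sik-targeted libraries, while replicates 2 and 3 did not. Tff1 stood at 447 CPM in replicate 1 and at 0.514 and 3.67 in replicates 2 and 3, against 177 to 1520 in Sik-targeted and 0.315 to 1.91 in KT libraries. Mcpt1 stood at 4020 against 2.16 and 8.45, with 745 to 2800 in Sik-targeted and 2.36 to 14.8 in KT libraries. Dpcr1 stood at 1240 against 3.39 and 20.6, and Dmbt1 at 1850 against 12 and 12.9. The hepatic and gut transcription factor Hnf4a stood at 194 CPM in replicate 1 and at 3.81 and 1.65 in replicates 2 and 3, with 41.6 to 165 in Sik-targeted and 2.38 to 10.4 in KT libraries. The surfactant gene Sftpc went the other way, with 537 CPM in replicate 1 and 19260 and 18750 in replicates 2 and 3, against 402 to 4390 in Sik-targeted and 7726 to 55540 in KT libraries. Stk11 stood at 9.23 CPM in replicate 1, below all KT and Sik-targeted libraries as in replicates 2 and 3 (16.6 and 9.92). Why replicate 1 differs was not tested, and neither a different tumour stage nor an exchange of samples was examined. Nkx2-1, the lung lineage factor, stood at 180 CPM in replicate 1 and at 173 and 332 in replicates 2 and 3, against 137 to 410 in Sik-targeted and 172 to 252 in KT libraries.

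Mcpt1, Mcpt2 and Mcpt8 rose in Sik-targeted libraries, and the tryptase Tpsab1, also chosen after its values were seen, stood at 5.95 to 37.1 CPM there against 0.212 to 0.803 in KT. The mast-cell carboxypeptidase Cpa3 had 0 counts in all 5 Sik-targeted libraries and up to 1.71 CPM in KT. Car9 and Stc1, both induced by hypoxia, parted in the Lkb1-deleted libraries. Car9 stood at 0.121, 0.617 and 1.47 CPM in replicates 1 to 3 and at 19.9 to 104 in Sik-targeted libraries, whereas Stc1 stood at 230, 88.2 and 86.3 CPM and at 177 to 426.

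Genes near Stk11 could differ between Lkb1-deleted and KT libraries because a strain haplotype is carried along with the floxed allele, given the mixed BL6/129 background. Within 10 Mb of Stk11 on chromosome 10, 2 of 201 tested genes (0.995%) were called for Lkb1 deletion against KT, against 153 of 12774 elsewhere (1.2%). The 1-sided Fisher exact p was 0.696. By the rule set beforehand, a share no higher than elsewhere spoke against the haplotype, and these shares met that rule. The interval of the odds ratio, 0.0988 to 3.09, also includes a modest excess. For this reason, given only after the value was seen, the hypothesis is left open.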
